A study of Mus musculus with 2 samples.

How the data were processed

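MicroRNA sequencing of total RNA, in a size range under 30 per the labels, gave 2 libraries of hippocampal tissue from male mice of the strain B6CASTF1/J at 18 to 20 months. The labels number them as biological replicates 1 and 2, with separate tissue entries and a shared donor entry, so both went into 1 group. Nothing in the labels says outright that the tissue came from separate animals, so the spread and the p-values measure differences between these samples, which may be technical.

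Each deposited table holds raw read counts per miRNA gene, in whole numbers and without normalization, after 4 summary lines for reads that were unmapped, mapped to several places, lay outside the annotated features or were ambiguous. Per the labels and the text deposited with the tables, the counts were made on mm10 with GENCODE annotation M21. The aligner and the counter are not given in the sources used here. A table has an unstranded count column and 2 stranded ones. No source used here says which stranded column is sense, so the one with the larger total was taken, as fixed before the data were examined. It held 3758318 counts in replicate 1 and 5598792 in replicate 2, against 287729 and 425273 for the other strand. The summary lines stayed out of library sizes and tests. Of all reads, 51.52% and 46.66% mapped to several places, 9.53% and 14.4% were unmapped and 3.47% and 4.24% lay outside the features, in replicates 1 and 2. A read that fits several gene copies enters no gene, so genes with near-identical copies are undercounted to an unknown degree.

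Symbols, coordinates and host genes came from GENCODE M21, which named all 2202 gene identifiers. A miRNA gene was called exonic when it overlaps an exon of any annotated transcript of a host gene on its strand. The longest sequence that each hairpin shares with any other annotated hairpin was taken from the annotated transcript sequences. CPM are counts per 1000000 sense counts over all miRNA genes. A gene was detected at 10 or more counts in both libraries. Intervals on shares are 95% Wilson intervals, and a count of 0 allows up to 3 counts, or 0.798 and 0.536 CPM in the 2 libraries, for genes whose reads map to 1 place. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The deeper library, replicate 2, had 457 genes with 10 or more counts and replicate 1 had 388.

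With 1 group there was no contrast between conditions. The spread between libraries was estimated with the edgeR common dispersion after TMM scaling. Each detected gene was tested with an exact two-sided binomial test of its counts, with the expected share taken from the TMM effective library sizes and Benjamini-Hochberg adjustment at 0.05. A chi-square statistic of 243102 on 383 degrees of freedom over detected genes was above sampling noise, so the tables are not 1 library deposited more than once. They were counted as 2 samples because the labels number them as separate replicates, which the statistic does not test. On simulated counts for the 384 detected genes of this comparison, the binomial test called 57 of 67 genes changed 1.5-fold, 62 of 67 changed 2-fold and 66 of 66 changed 4-fold, 5 unchanged genes (2.7%) in that mixture, and 0 when none was changed. The simulated counts held counting error only, with no spread between samples, and were tested without TMM scaling. These rates therefore do not cover calls that arise from spread between samples. Simulated coefficients of variation of 0.1, 0.3 and 0.5 were estimated at 0.0996, 0.301 and 0.493. A fold between libraries is on the TMM scale unless CPM is named, and the scales differ by a factor of 1.25.

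There were 22 gene lists for cell types, other tissues, families and clusters, fixed before the data were examined, as were the rule for named genes and all alternatives except those named as added. A list's level is its summed CPM, and its rank is the percentile of its median gene among 10000 random lists of the same size, a description of these libraries with no p-value. Lists can share members: Mir21a is in the astrocyte and the ageing-linked lists. The member mir-146a matched no symbol because the annotation calls it Mir146, and it stayed out of both lists that name it. The named genes are the 20 most abundant, the 3 highest members of each list, the 5 largest ratios between libraries among called genes with at least 100 counts in each, and the members of families with identical copies. Genes named outside that rule are said to be so.

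Alternatives were the unstranded or opposite-strand counts, other detection limits, no filter, pseudocounts of 0.1 and 10 in place of 1, DESeq2 size factors or total counts in place of TMM, a chi-square test, other denominators, random lists of detected genes, and each replicate left out. Removing list members that share at least 20 nt with another hairpin, and adding Mir146 to the microglia and leukocyte list, were chosen after seeing the data, as were the mir-17 to 92 list without Mir92b and the Sfmbt2 and Dlk1-Dio3 lists on chromosomes 2 and 12 only. A level was taken as moved when it changed by more than 1 SD. The margin was 1.4 percentage points for the coefficient of variation, at least 1 point for ranks, and the 95% interval over genes for correlations. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.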

Results

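Small RNA was profiled by microRNA sequencing in hippocampal tissue of aged male mice. MicroRNAs are short RNAs that lower the translation or stability of the messenger RNAs they pair with, and each is cut from a hairpin encoded by a miRNA gene. The animals were F1 hybrids of the C57BL/6 and CAST/Ei backgrounds, 18 to 20 months old. There was 1 group with 2 libraries, replicate 1 and replicate 2, so no treatment, age or sex was compared. The design allowed a description of which miRNA genes this tissue used, at what level, and how far the replicates differed. Replicate 1 had 10594081 reads, of which 3758318 (35.48%, Wilson 95% interval 35.45 to 35.50%) were counted on the sense strand of miRNA genes. Replicate 2 had 16131923 reads, of which 5598792 (34.71%, interval 34.68 to 34.73%) were counted.

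Let-7 genes dominated the counted reads of the hippocampal libraries. Shares below are of counted reads, so reads that mapped to several places are not in them. Mirlet7g alone held 156275 ± 19619 counts per 1000000 counted reads (CPM; mean ± SD, n = 2 here and for every mean below), or 15.6% ± 1.962 of all counted reads. Mirlet7b followed at 81054 ± 3457 CPM, Mir139 at 74862 ± 6414 CPM and Mirlet7i at 69138 ± 10760 CPM. Of the 2202 annotated miRNA genes, 384 (17.4%) had at least 10 counts in both libraries and were taken as detected, and 1450 (65.8%) had no count in either. The 10 most abundant genes held 56.9% ± 1.45 of the counts and the 50 most abundant 88.8% ± 1.15.

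In the mm10 genome, Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 from 106178840 to 106178927 in an intron of Wdr82. Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15 from 85707319 to 85707403 in an exon of the non-coding gene Lncppara. Mir139 (ENSMUSG00000065446.1) lies on chromosome 7 from 101475376 to 101475443 in an intron of Gm45837. Mirlet7i (ENSMUSG00000065406.3) lies on chromosome 10 from 122985640 to 122985724 in an exon of D630033A02Rik. The next ranks were taken by Mirlet7d (35984 ± 13898 CPM), Mir744 (35550.4 ± 10085 CPM), Mir99a (32952 ± 9308 CPM), Mir127 (29992 ± 174 CPM), Mir23b (28859 ± 937 CPM) and Mirlet7e (24326 ± 986 CPM). Between 11253 and 20409 CPM stood Mir29a, Mir132, Mir26b, Mir191, Mir151, Mir128-1, Mir137, Mir23a, Mir126a and Mir125a, in falling order. Of these, Mir125a had the widest spread relative to its level, with 5924 CPM in replicate 1 and 16583 CPM in replicate 2.

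**Figure D1:**
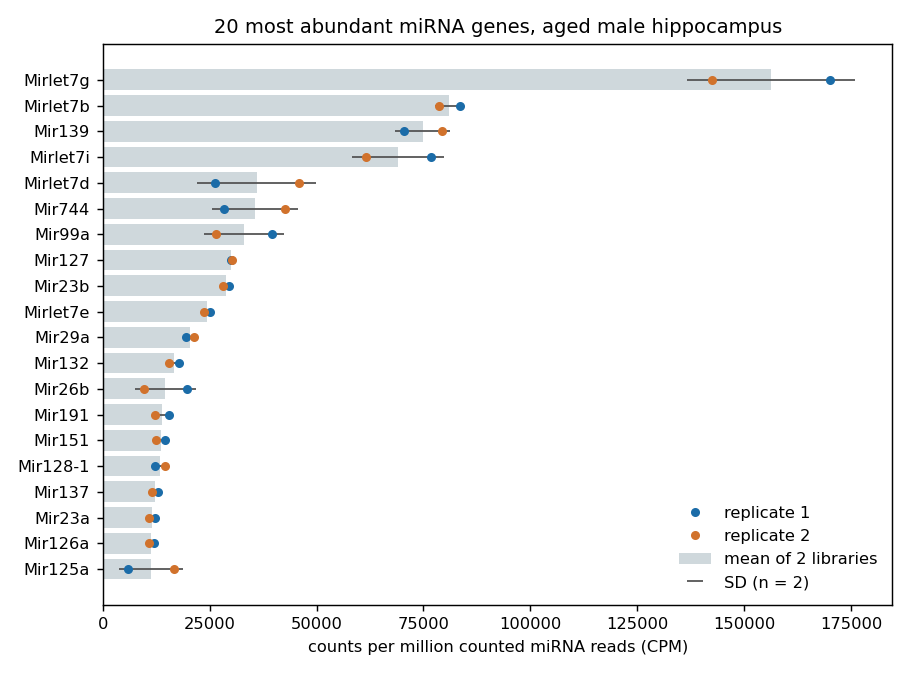
Level of the 20 most abundant miRNA genes, in CPM on a linear axis from 0. Bars are means of 2 libraries, lines the SD and points the libraries; Mirlet7g, at 156275 CPM, stands above Mirlet7b at 81054 CPM, and Mir125a spans 5924 to 16583 CPM.

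MicroRNAs described as enriched in neurons were abundant. The 15 genes of that list summed to 53429 ± 1995 CPM, and 11 of them were detected. Mir132, which neuronal activity induces, had 16652 ± 1642 CPM (chromosome 11, 75173682 to 75173747), Mir128-1 had 13309 ± 1589 CPM (chromosome 1, 128202361 to 128202430, intron of R3hdm1) and Mir137 had 12226 ± 884 CPM (chromosome 3, 118433857 to 118433929). The astrocyte list (7 of 7 detected) summed to 26926 ± 3.23 CPM, of which Mir29a gave 20409 ± 1270 CPM, Mir21a 2605 ± 1230 CPM and Mir29c 2324 ± 222 CPM. The small SD of the sum hides offsetting differences between members in CPM. In replicates 1 and 2, Mir29a had 19511 and 21307 CPM, and Mir21a had 3475 and 1735 CPM. On the TMM scale both genes were higher in replicate 1, by 1.14-fold and 2.49-fold. On that scale 5 of the 7 members were called higher in replicate 1 and 2 in replicate 2. The oligodendrocyte list (2 of 5 detected) summed to 7902 ± 2559 CPM, with Mir338 at 4986 ± 2692 CPM and Mir219a-2, a microRNA of myelinating cells, at 2911 ± 136.04 CPM.

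Genes listed for other cells in brain tissue were also read, though counts of whole tissue do not show which cells the reads came from. The endothelial and mural list (3 of 5 detected) summed to 19278 ± 3914 CPM, from the endothelial Mir126a at 11290 ± 797 CPM (in an exon of Egfl7), the smooth muscle gene Mir143 at 7591 ± 2870 CPM and Mir145a at 397 ± 247 CPM. The microglia and leukocyte list (5 of 6 detected) summed to 2955 ± 178 CPM, with Mir342 at 2121 ± 145.4 CPM, Mir150 at 648 ± 15.6 CPM and Mir142 at 126.7 ± 19.1 CPM. The choroid plexus and ependyma list (7 of 10 detected) summed to 2647 ± 744 CPM, led by Mir34c at 1328 ± 231 CPM, Mir204 at 898 ± 197 CPM and Mir1298 at 255 ± 246 CPM. The sensory cluster (2 of 3 detected) reached 137.8 ± 41.3 CPM, with Mir182 at 70.8 ± 28.2 CPM and Mir183 at 63.97 ± 9.56 CPM. The erythroid list (3 of 4 detected) reached 79.5 ± 22.9 CPM, including the red cell gene Mir451a at 51.5 ± 16.8 CPM.

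Against 10000 random lists of the same size drawn from all miRNA genes, the median gene of each list lay at percentile 100 for neurons, 99.99 for astrocytes, 96.6 for oligodendrocytes, 99.2 for microglia and leukocytes, 99.8 for endothelial and mural cells and 99.9 for choroid plexus. The sensory cluster lay at 97.7 and the erythroid list at 93.1. As 65.8% of all miRNA genes had no count in either library, a high percentile can come with few counts. The median gene of the oligodendrocyte list had 4.01 CPM. Against detected genes alone, the percentile was 54.9 for the microglia and leukocyte list, 37.8 for the choroid plexus list and 15.8 for the erythroid list. With the unstranded counts, which drop reads where miRNA genes overlap on opposite strands, the sum was 0.193 CPM for the oligodendrocyte list, 8649 CPM for the endothelial list and 14.3 CPM for the erythroid list. Without members that share at least 20 nt with another hairpin, the neuron list summed to 29232 CPM and the oligodendrocyte list to 4986 CPM.

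MicroRNAs of tissues other than brain had fewer counts than most lists for cells in brain tissue. The sensory cluster (137.8 CPM) and the erythroid list (79.5 CPM) were exceptions, below the epithelium list and the liver list. The epithelium and skin list (6 of 7 detected) summed to 328.7 ± 14.5 CPM, with Mir203 at 163 ± 73.7 CPM, Mir429 at 60.02 ± 12.6 CPM and Mir200c at 53.7 ± 24.8 CPM. The liver and pancreas list (2 of 6 detected) reached 326 ± 34.1 CPM, from the endocrine Mir375 at 288 ± 18.6 CPM and the hepatocyte gene Mir122 at 35.7 ± 16.7 CPM, while Mir217 had 1.33 ± 1.13 CPM. The muscle list (2 of 11 detected) reached 82.4 ± 17.6 CPM, with Mir206 at 65.9 ± 19.5 CPM, Mir499 at 9.16 ± 4.36 CPM and Mir208a at 3.03 ± 2.03 CPM. Genes of the Hox clusters (4 of 6 detected) reached 55.9 ± 9.36 CPM, with Mir10a at 28.9 ± 1.68 CPM, Mir10b at 16.1 ± 8.86 CPM and Mir196b at 5.97 ± 0.91 CPM. None of the 14 genes of pluripotent cells and none of the 18 genes of the testis X cluster was detected, and their sums of 1.83 ± 0.701 and 1.02 ± 0.436 CPM came from a few reads, with Mir302d at 0.756 ± 0.0592 CPM and Mir741 at 0.667 ± 0.186 CPM. A count of 0 allows up to 0.798 CPM in replicate 1 and 0.536 CPM in replicate 2 for a gene whose reads map to 1 place. It sets no upper limit for genes whose reads map to several copies, and 6 of 11 muscle, 6 of 18 testis X and 4 of 14 pluripotent cell genes share at least 20 nt with another hairpin. The median gene lay at percentile 99.5 of random lists for epithelium and skin, 95.9 for the Hox clusters, 90.2 for liver and pancreas, 41.6 for pluripotent cells and 43.9 for the testis cluster. Against detected genes alone it lay at 21.2 for epithelium and skin and 4.53 for the Hox clusters. The muscle list stood at percentile 87.8 with both libraries and at 46.2 without replicate 2.

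**Figure D2:**
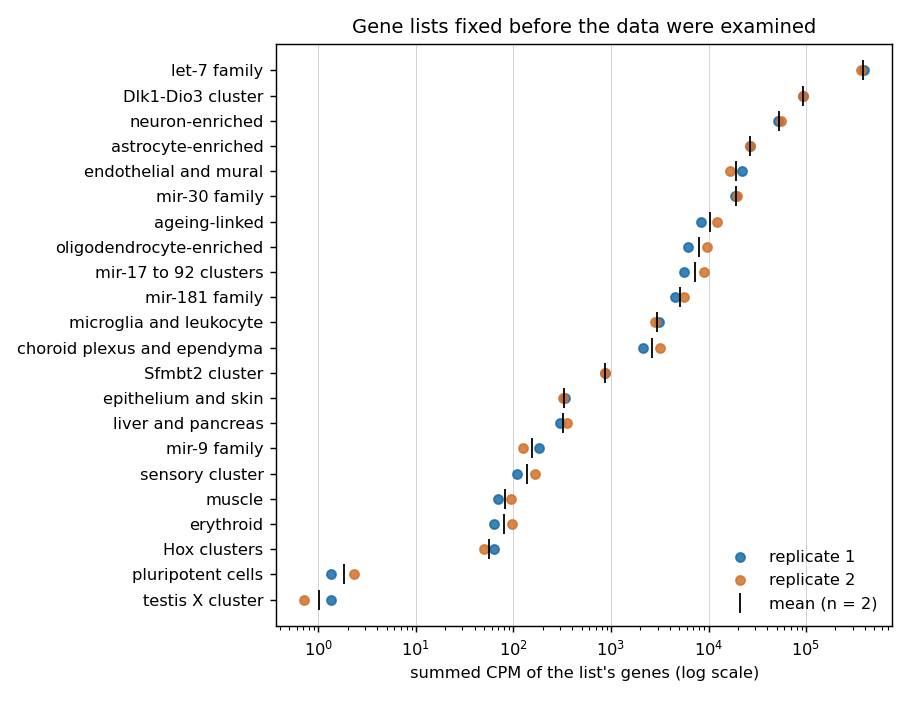
Summed CPM of each of the 22 gene lists, on a log axis. Points are the 2 libraries and ticks their mean (n = 2); the lists run from 1.02 CPM for the testis X cluster to 382099 CPM for the let-7 family.

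Families and genomic clusters accounted for much of the counted reads. All 12 let-7 family genes were detected and held 38.2% ± 2.15 of the counts. The imprinted Dlk1-Dio3 cluster on chromosome 12, expressed from the maternal allele, had 44 of its 49 listed genes detected (a further listed gene, Mir496b on chromosome 19, had no counts and was named after its value was seen) and held 9.37% ± 0.00841, that is 93645 and 93764 CPM in the 2 libraries. Its leading genes were Mir127 (29992 ± 174 CPM), Mir411 (7757 ± 1328 CPM) and Mir382 (7191 ± 510 CPM). The share leaves out unlisted genes that lie between the listed ones. Among them were Mir370 and Mir341, with means of 900 and 878 CPM, named after their values were seen. The small SD holds for the sum of the listed genes in CPM, and not for single genes. The CPM and TMM scales differ by a factor of 1.25, so a near-equal CPM is a lower level in replicate 2 on the TMM scale. Mir127, for one, was 1.24-fold higher in replicate 1 on that scale. Of the 44 detected, the binomial test called 35, 19 higher in replicate 1 and 16 higher in replicate 2 on the TMM scale. The mir-30 family (6 of 7 detected) summed to 19160.5 ± 441 CPM, with Mir30e at 7456 ± 1459, Mir30a at 5993 ± 653.9 and Mir30d at 5252 ± 378.8 CPM. The mir-17 to 92 list (11 of 16 detected) summed to 7315 ± 2402 CPM, but 4714 ± 1962 CPM of this came from Mir92b, a related gene on chromosome 3 outside the clusters. The other 15 genes (10 detected) summed to 2601 ± 439.6 CPM, with Mir93 at 1274 ± 30.3 and Mir17 at 461 ± 24.0 CPM. The mir-181 family (6 of 6 detected) summed to 5075 ± 766 CPM, led by Mir181c at 1699 ± 448.3 and Mir181d at 1589 ± 84.5 CPM. The Sfmbt2 list had 8 of 81 genes detected, all among its 71 members on chromosome 2, and summed to 867 ± 5.29 CPM, led by Mir467d at 305 ± 57.3 and Mir467e at 267 ± 63.1 CPM. Of the 81 genes, 79 share at least 20 nt with another hairpin and the other 2 had no counts, so the sum is not a tissue level. Genes often described as higher in aged or inflamed brain (6 of 6 detected) summed to 10304 ± 2642 CPM, with Mir22 at 6044 ± 3675 CPM, Mir21a at 2605 ± 1230 CPM and Mir125b-1 at 634 ± 28.3 CPM. The series holds 1 age, so these are levels and not changes.

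The median gene stood at percentile 100 of random lists for the let-7 family and for Dlk1-Dio3. It stood at 99.9 for the mir-30 family and for the ageing-linked list, 99.95 for the mir-181 family, 99.96 for the mir-17 to 92 list, 95.6 for the mir-9 family and 49.96 for the Sfmbt2 list, which was at 19.6 against detected genes alone. The mir-30 family summed to 12670 CPM with the unstranded counts, and the mir-181 family to 3288 CPM without members sharing at least 20 nt.

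Some families whose hairpins share a stretch of at least 20 nt had low or uneven counts. The 3 copies of Mir124a, a microRNA known as abundant in neurons, had 2 and 5 counts (Mir124a-1), 0 and 2 counts (Mir124a-2) and no count (Mir124a-3) in replicates 1 and 2. The mir-9 family (2 of 3 detected) summed to 154.1 ± 42.1 CPM, nearly all from Mir9-3 at 138.05 ± 31.3 CPM, beside 14.7 ± 10.1 CPM for Mir9-1 and 1.38 ± 0.686 CPM for Mir9-2. Mirlet7a-1 had 319 ± 9.86 CPM, Mirlet7a-2 had 164 ± 50.3 CPM, and Mir7-2 and Mir7-1, which share 24 nt, had 183.06 ± 105.4 and 126.2 ± 45.6 CPM. In other such families a copy was well counted: Mir138-1 had 4458 ± 1234 CPM, Mir128-2 2538 ± 73.2 CPM and Mir181a-1 723 ± 81.2 CPM. Reads that mapped to several places numbered 5458072 in replicate 1 (51.52%, interval 51.49 to 51.55%) and 7527048 in replicate 2 (46.66%, interval 46.63 to 46.68%). Those reads are not assigned to genes in the counts, so the levels of genes that share sequence with another hairpin are uncertain and are not tissue levels.

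The replicates ranked genes alike but differed beyond counting error. Across the 384 detected genes, log2(CPM + 1) correlated with a Pearson coefficient of 0.980 and a Spearman coefficient of 0.977, over genes, which are not independent replicates. The biological coefficient of variation was 34.2% (edgeR common dispersion). An exact two-sided binomial test per gene, with TMM-scaled library sizes and Benjamini-Hochberg adjustment, called 250 of 384 genes (65.1%), 131 higher in replicate 1 and 119 higher in replicate 2. The median absolute difference over all detected genes was 1.36-fold, and 57 called genes differed by at least 2-fold. The test compares these libraries, not conditions. With total-count scaling, which raises the median log2 ratio from -0.02 to 0.30, 271 genes were called, 76 higher in replicate 1 and the others (72.0%) higher in replicate 2.

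The 5 largest called ratios among genes with at least 100 counts in each library, on the TMM scale, were as follows. Mir674 (chromosome 2, 117185127 to 117185226) was 4.59-fold higher in replicate 1, with 15626 and 6322 counts in replicates 1 and 2. Mir140, in Wwp2 (chromosome 8, 107551244 to 107551313), was 3.99-fold higher in replicate 1, with 12654 and 5885 counts. Mir380 of the Dlk1-Dio3 cluster (chromosome 12, 109711803 to 109711863) was 3.93-fold higher in replicate 1, with 1420 and 671 counts. Mir1298, in an intron of the serotonin receptor gene Htr2c (chromosome X, 147064905 to 147065002), was 4.24-fold higher in replicate 2, with 304 and 2397 counts. Mir106b, in an intron of Mcm7 (chromosome 5, 138165737 to 138165818), was 4.19-fold higher in replicate 2, with 388 and 3018 counts. On the same scale and test, called members of the neuron list (11 of 11 detected) went both ways, 6 higher in replicate 2 and 5 in replicate 1. The choroid plexus list had 5 of 7 detected members called, each higher in replicate 2, and the endothelial and mural list had 3 of 3 called, each higher in replicate 1. These 3 counts were the same when adjusted over the list alone.

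**Figure D3:**
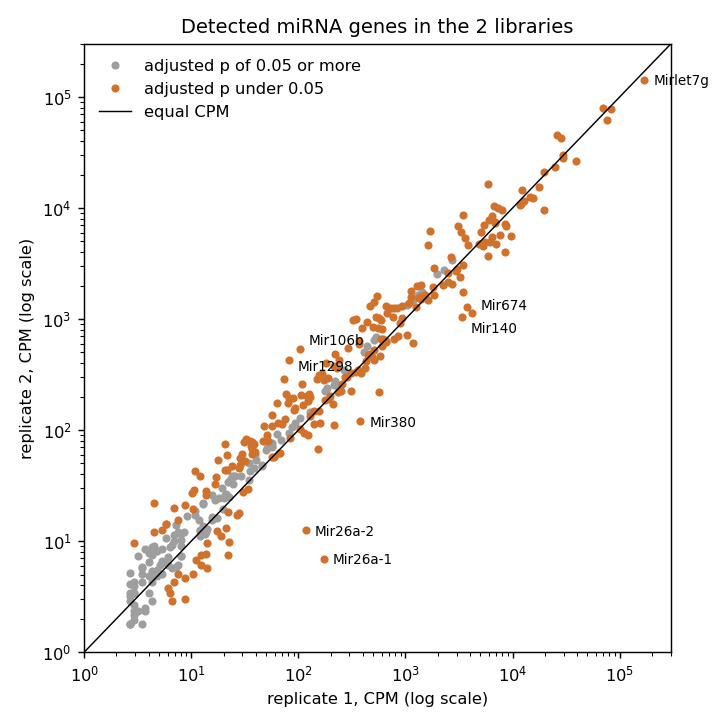
CPM of the 384 detected miRNA genes in replicate 1 and replicate 2, on log axes; the line marks equal CPM, and orange points had an adjusted p under 0.05 in the exact binomial test on TMM-scaled library sizes. Most genes lie near the line (Pearson coefficient 0.980), with Mir674, Mir140 and Mir380 below it and Mir1298 and Mir106b above it. Mir26a-1 and Mir26a-2, also below it, were chosen for marking after their values were seen.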

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

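The tests on let-7 copies and on the choroid plexus list, and 4 further tests on gene pairs, were chosen only after the result was seen. The tests on neighbours, GC content and related sequences were written down before they were run, but after counts of single genes such as Mir125a had been read.

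The opposite-strand count column, whose totals served to choose the sense column and as an alternative, held 287729 counts in replicate 1 and 425273 in replicate 2. Of these, 99.97% in each library lay in genes that overlap a miRNA gene on the other strand, and those totals, 287630 and 425131, equal the numbers of reads that were ambiguous without strand. Gm25927 had 94045 and 132290 opposite-strand counts, the same as the sense counts of Mirlet7e on its other strand, so these are reads the report already counts for the partner gene and not a further signal. Genes with no such partner held 0.0344% and 0.0334% of the opposite-strand counts, led in the sum of both libraries by Mir3083 with 15 and 23 counts. Gm25927 and Mir3083 were chosen after their values were seen.

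Mir124a and Mir9 genes held 184 CPM in replicate 1 and 125.6 CPM in replicate 2, summed over 6 copies. A candidate explanation is that reads shared by gene copies were not counted. Each of the 6 copies shares at least 26 nt with another hairpin, and among let-7 genes the 6 that share at least 20 nt had a median of 406 CPM against 52561 CPM for the other 6 (exact permutation test, one-sided, p = 0.00108). Those let-7 groups did not overlap, with at most 4755 CPM against at least 7795 CPM, so the p-value is the smallest possible. The test was chosen after the values were seen, so its p-value restates that order and is not independent support. Sharing alone does not empty a gene, as Mir128-1 shares 23 nt with another hairpin and had 13309 CPM. A low tissue level cannot be told apart from this, because reads mapped to several places were at least 1.34 times the counted reads (1.344 in replicate 2) and no table splits them by gene.

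The libraries differed beyond counting error in 250 of 384 genes, and 3 explanations were tested on the 242 genes with at least 100 counts in each. Neighbours were genes within 10 kb on 1 strand that share under 12 nt, so sequence-related neighbours were left out. A difference in transcription of their locus would move neighbours together. They differed in log2 ratio by 0.73 on average against 0.73 for reassigned ratios (239 pairs, permutation test, one-sided, p = 0.527, adjusted p = 0.79 over 6 tests). The adjusted p of that test was 0.963 both without Dlk1-Dio3 genes and with loci weighted equally. These values argue against locus transcription as the main source across the 96 genes with such neighbours. Most of these pairs involved Dlk1-Dio3 genes. The 34 pairs without them differed by 0.92 against 0.73. A smaller part from locus transcription was not excluded. GC content of the hairpin gave an R squared of 0.06 across genes, which argues against it as the whole source. Genes at separate loci that share at least 12 nt had closer ratios, 0.50 against 0.73 (102 pairs, permutation test, one-sided, p = 0.00047, adjusted p = 0.00282), also without let-7 genes (adjusted p = 0.0268), and for the 36 pairs of genes sharing under 20 nt with every hairpin the values were 0.53 against 0.73 (raw p = 0.0275, adjusted p = 0.0549, with fewer pairs). A sequence-dependent step in library making or mapping may contribute, and regulation of microRNAs by sequence family was not separated from it, nor were differences between the tissue samples.

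In the choroid plexus list, all 7 detected members had ratios of replicate 2 to replicate 1 above 1 on the TMM scale, and 5 were called, the same number when adjusted over the list alone. Mir1298, Mir1264 and Mir448, all in introns of Htr2c, were 4.24, 2.22 and 2.15-fold higher in replicate 2, while Mir34b, Mir204, Mir34c and Mir449a stood at 1.59, 1.10, 1.03 and 1.02-fold (Mir1264, Mir448, Mir34b and Mir449a were named after their values were seen). Random lists matched on expression had a median log2 ratio of 0.163, and the 4 members outside Htr2c had a median of 0.0871. More choroid plexus or ependymal tissue in the sample of replicate 2 cannot be told apart from chance. The median log2 ratio of all 7 members, 0.67, lay at percentile 95.68 of those random lists. A linear GC trend accounted for -0.0455 (95% interval -0.275 to 0.058) of the median's log2 excess of 0.503 over those lists, which argues against GC content as the whole source; this is the third form of a test revised each time after values were seen, and the form before it, percentile 97.58 without the trend, decided nothing. Higher transcription of Htr2c stays open and untested, because its 3 members were set against the other 4 only after they were seen to have the largest ratios, and the exact permutation p of 0.0286, the smallest possible, restates that order.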

How the results depend on the processing

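Removal of sharing members or of Mir92b, the restriction of the Sfmbt2 list to chromosome 2 and of the Dlk1-Dio3 list to chromosome 12, and the addition of Mir146 were chosen after seeing the data, and unless stated the cause of a move was not tested. No paired analysis was possible because there is 1 group. The planned removal of members whose hairpin has no sequence found once in the genome was not run, as no genome sequence was used here, and the mir-9 family kept no member without sharing ones.

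With unstranded counts, which lose overlapping genes as ambiguous, replicate totals were 3470787 and 5173803 and the 10 top genes held 61.2%; the opposite strand had 287729 and 425273. A limit of 1 count gave 597 genes, and 117 differing genes were also 1.5-fold apart. Without a filter the correlations were 0.986 (Pearson) and 0.929 (Spearman) and the coefficient of variation 36.5%. With the filter kept and total counts in place of TMM it was 37.0%. DESeq2 size factors called 250 genes.

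Unstranded list sums were, in CPM, neuron 56800, astrocyte 29147, oligodendrocyte 0.193, erythroid 14.3, endothelial 8649, epithelium 357, mir-30 12670, Dlk1-Dio3 95402 and Sfmbt2 939. Their percentiles were oligodendrocyte 39.9, erythroid 29.7, endothelial 88.2, muscle 44.1, pluripotent 42.8, testis 45.0 and mir-9 90.3. Without Mirlet7g in the denominator, sums rose by construction: neuron 63315, astrocyte 31922, microglia 3506, Hox 66.4, liver 386, epithelium 389.9, let-7 453291, mir-30 22709.5, mir-181 6006, Dlk1-Dio3 111089 and Sfmbt2 1028. Without sharing members they fell by construction: neuron 29232, astrocyte 24496, oligodendrocyte 4986, pluripotent 0.756, mir-181 3288, Dlk1-Dio3 78646 and Sfmbt2 0. With Mir146 the microglia list had 3595 ± 214 CPM, without Mir92b the mir-17 to 92 list had 2601, on chromosome 2 the Sfmbt2 list had 867 and on chromosome 12 the Dlk1-Dio3 list had 93704.5.

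Among detected genes only, a background of higher level, percentiles were astrocyte 96.6, microglia 54.9, erythroid 15.8, endothelial 98.65, choroid 37.8, Hox 4.53, epithelium 21.2, mir-30 97.75, mir-181 89.9, mir-17 to 92 74.5, Sfmbt2 19.6 and ageing-linked 83.4. With a replicate left out, ranks ranged from 43.9 to 45.6 for pluripotent cells, 45.9 to 47.3 for the testis cluster and 46.2 to 91.8 for muscle, whose median gene is near 0 counts. For list sums, gene levels and the top-10 share, each of 2 libraries lies within 1 SD of their mean by construction, so leaving a replicate out says nothing about their stability; detected genes numbered 388 to 457. Among named genes, 43 of 102 levels moved without Mirlet7g in the denominator, 37 with unstranded counts and 84 with all reads in the denominator. Depth limits genes near 10 counts, and the counts cannot show levels of genes whose reads map to several copies.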

Other observations

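Genes in this part were chosen after their values were seen, unless they are among the named genes of the report. Among abundant genes outside the lists were Mir221 (8848 ± 1134 CPM) and Mir652 (6235 ± 1165 CPM) on chromosome X, Mir328 (8674 ± 2005 CPM), Mir330 in Eml2 (8538 ± 2568 CPM), and Mir335 in an intron of the imprinted gene Mest (4951 ± 542.6 CPM). Of the counts, 52.5% ± 1.63 came from miRNA genes in introns, 31.0% ± 1.43 from genes overlapping exons and 16.5% ± 0.195 from genes outside others on their strand. Chromosome 9, which carries Mirlet7g, gave 18.6% ± 2.16 of the counts. Chromosome 12 gave 9.96% ± 0.0281 and had 41.8% of its miRNA genes detected, against 10.8% (28 of 259) on chromosome 2. The Sfmbt2 list members there had a like share, 8 of 71. Mir146, left out of 2 lists by its name, had 639.7 ± 35.3 CPM.

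Members of the mir-26 family were lower in replicate 2 at 3 loci. Mir26a-1 in Ctdspl had 650 and 39 counts in replicates 1 and 2, and Mir26a-2 in Ctdsp2 had 440 and 70, differences of 30.6-fold and 11.6-fold on the TMM scale that exceed those of the report's 5 genes but fall under 100 counts in a library. Mir26b in Ctdsp1 had 73643 and 53313 counts, 2.56-fold lower in replicate 2 on that scale. Mir26a-1 and Mir26a-2 each share 25 nt with another hairpin, so reads that fit several copies are missing from their counts. Their ratios need not follow the tissue level. The mir-99 family was also lower in replicate 2 at 3 loci, Mir99a by 1.87-fold, Mir99b by 2.64-fold and Mir100 by 1.83-fold. Within the cluster on chromosome 17 from 17830188 to 17830879, in Spaca6, genes went apart: Mir99b had 8572 and 4048 CPM, Mirlet7e 25023 and 23628 CPM, and Mir125a 5924 and 16583 CPM. Mir106b and Mir93 are neighbours in Mcm7, and Mir106b was 4.19-fold higher in replicate 2 while Mir93 was 1.20-fold higher in replicate 1 on the TMM scale, with CPM of 1253 and 1296.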
